A study of Saccharomyces cerevisiae with 29 samples.

How the data were processed

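The series describes 29 libraries of 14 budding yeast strains made by HydEn-seq, which sequences the DNA 5′ ends left when alkali cuts genomic DNA at incorporated ribonucleotides. Groups were taken from the strain label of each library. The 14 strains are 7 DNA polymerase backgrounds, each with RNH201 and without it. The submitters' processing notes name cutadapt 1.2.1 and Bowtie 0.12.8, with no parameters given in the sources used here. End counts of the libraries were not analysed here, so no value in this text belongs to a library, no depth per library is given and no strain is compared with another.

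The 1 processed file used was the annotation of L03, the reference sequence for these strains. Per the file header, the authors derived it from version R64-1-1 of the S288C genome in the Saccharomyces Genome Database. How features were moved to L03 is not given in the sources used here. The file gives a type, a start, an end and a strand per feature, numbered from 1 on 16 chromosomes, and its score column is empty. All coordinates below are on L03 (ref_v2) and not on R64. The file gives no value with an error, so intervals and permutation tests below describe features along 1 sequence, not replicates.

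Genes were the 5859 gene features with an annotated mRNA, less 2 reading frames that the annotation calls dubious, which left 5857. Genes whose coding sequence carries a qualifier of experimental evidence, 4727 of them, formed a stricter set. Origins were the 274 features typed as origins of replication, each taken at its midpoint. Only 4 of them carry a qualifier of experimental evidence, and a missing qualifier does not show that evidence is absent. A gene pointed away from an origin if it was transcribed in the direction leading from that origin past the gene's midpoint. An origin was intergenic if its midpoint lay in no protein-coding gene. Gene features such as those of POL1, POL2, POL3 and RNH201 were as long as their coding sequences, so untranslated sequence beside them counted as intergenic. The genes on either side of an intergenic origin were called convergent, divergent or tandem by their strands.

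Shares were tested with two-sided permutation tests. For gene orientation and intergenic position, the origins of each chromosome were shifted together by a random amount around the chromosome, 10000 times, with genes fixed. For gene pairs, origins were placed at random in the gaps between genes, in proportion to gap length. For spacing, the same number of origins was placed at random on each chromosome, and the coefficient of variation of the distances was tested. Gene lists were compared with all other genes by Fisher's exact test with Benjamini-Hochberg adjustment over the 7 lists. Intervals are exact Clopper-Pearson 95% intervals of a count. Both these intervals and Fisher's exact test treat features as independent, which neighbours are not. The tests of gene orientation, intergenic position, gene pairs, spacing and gene lists, the lists themselves and the alternatives were fixed before the data were examined. The 6 distance classes, the test without the genes beside origins, the relation of origin number to chromosome length and the tests on other features and on coding length were chosen afterwards. Alternatives changed which genes count, the distance limit, the gene position used, the overlap rule, the random placement and the chromosome ends or chromosomes left out. The rule for named genes took POL1, POL2, POL3 and RNH201, and for each list the 2 members nearest to an origin and the 2 farthest from one. It also took the 5 longest and 5 shortest distances between origins and the 5 genes whose length differed most from the reference, of which 1 is not reported here.

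That last comparison was planned against the R64 gene table. As the table is on another build, it was used only for names and gene order, and lengths were compared inside the L03 file instead, between the coding sequence and the protein length stated for it. Of 6002 nuclear protein-coding genes in the table, 5852 had an entry under the same locus tag, and the others were not analysed here. Of the 5857 genes analysed, 5848 were matched, and 594 of these have another symbol in the table. Names below are those of the L03 file. Of 5832 pairs of neighbouring matched genes, 5830 were also neighbours in the table.

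The orientation test was tested on simulated data with the real gene and origin positions and strands drawn anew for 5857 genes, against a smaller number of shifts than the real data. With 50% of genes set to point away, 0 of 20 simulations fell below 0.05. With 55% and with 60%, 20 of 20 did so, and the mean recovered shares were 54.8% and 60.0%. Strands were drawn independently for each gene and with the same share at every distance. The simulations therefore do not cover the shares near origins, nor any dependence between neighbouring genes. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.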

Results

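The libraries were designed to map ribonucleotides left in the genome of budding yeast strains whose replicative DNA polymerases were altered, with or without RNase H2. Of the 29 libraries, 13 came from 7 strains with RNH201 and 16 from 7 strains without it. The wild type and the rnh201-delta strain had 2 libraries each. The DNA polymerase epsilon variant pol2-M644G had 3 libraries with RNH201 and 4 without it, and pol2-M644L had 2 and 2. The DNA polymerase delta variant pol3-L612G had 2 and 2, and pol3-L612M had 1 and 2. The DNA polymerase alpha variant pol1-Y869A had 2 and 3, and pol1-L868M had 1 and 1. The ribonucleotide signal of these libraries was not analysed here, so the comparisons between strains that this design implies have no values below. The results describe the genome on which those ends were to be placed, which is the altered loci, the origins from which leading and lagging strands start, and the genes around them.

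All 4 altered genes were present in the L03 annotation at full length, in 1 exon each and on the plus strand. POL1 (YNL102W), the catalytic subunit of DNA polymerase alpha, lay on chromosome XIV from 430042 to 434448. By the residue numbers in the strain names, the codon altered in pol1-L868M falls at 432643 to 432645 and that altered in pol1-Y869A at 432646 to 432648. POL2 (YNL262W), the catalytic subunit of DNA polymerase epsilon, lay on chromosome XIV from 148164 to 154832, with the codon altered in pol2-M644G and pol2-M644L at 150093 to 150095. POL3 (YDL102W), the catalytic subunit of DNA polymerase delta, lay on chromosome IV from 276811 to 280104, with the codon altered in pol3-L612G and pol3-L612M at 278644 to 278646. RNH201 (YNL072W), the catalytic subunit of RNase H2, lay on chromosome XIV from 490273 to 491196. The coding sequences of the 4 genes had the lengths that their stated proteins of 1468, 2222, 1097 and 307 residues require, with 0 bp of difference. The altered codons are all in coding exons, and the bases there were not analysed here.

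RNH201 lay closest to an annotated origin, with its midpoint 8.33 kb from ARS1420. POL1 was 17.2 kb from ARS1419, POL2 was 18.1 kb from ARS1411, and POL3 was 24.6 kb from ARS410. POL1, POL2 and RNH201 pointed toward their nearest origin and POL3 pointed away from it.

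**Figure D1:**
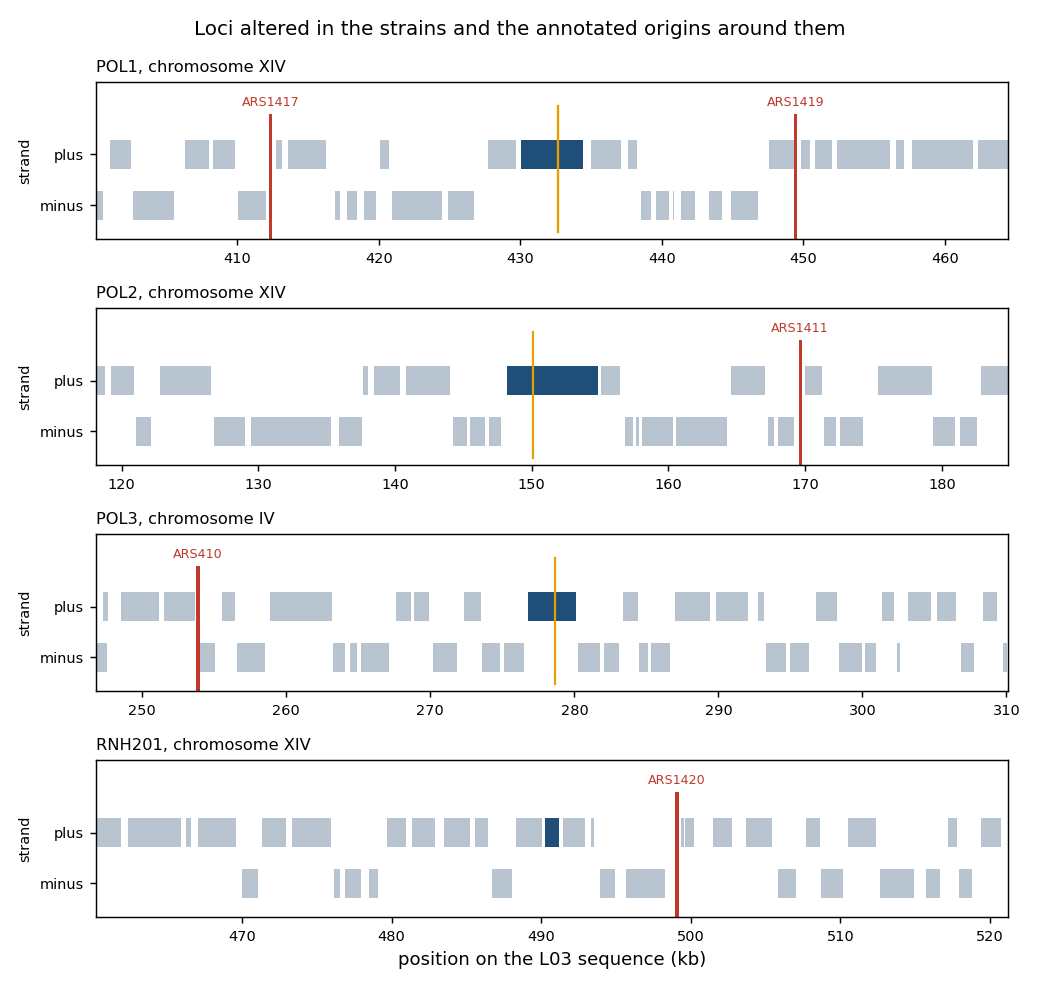
Map of the 4 altered loci on the L03 sequence (horizontal axis, position in kb), with 30 kb on each side. Dark boxes are the altered genes and pale boxes other protein-coding genes, each on its strand, red bars are annotated origins to scale and yellow lines the altered codons. The nearest origin lies 8.33 kb from the midpoint of RNH201 and 24.6 kb from that of POL3.

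The reference also carried marks of strain construction at loci other than these. AGP1, an amino acid permease gene on the minus strand of chromosome III, was interrupted by an insert of 1234 bp at 76087 to 77320 that held URA3, which encodes an enzyme of uracil synthesis, on the plus strand at 76347 to 77150. The coding feature of AGP1 spanned 1956 bp where its stated protein of 633 residues requires 1902 bp. That span includes the insert of 1234 bp, so less than 1902 bp of AGP1 itself remained. At LEU2, an enzyme gene of leucine synthesis on chromosome III, 58 bp of coding sequence remained of 1095 bp, overlapping a site of 187 bp marked for insertion of KanMX. On chromosome V a mark of 5 bp at 115947 to 115951 stood at a ura3 deletion. The strain labels name neither AGP1, LEU2 nor URA3.

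The annotation covered 12.06 Mb on 16 chromosomes, with 5857 genes used below, 275 tRNA genes, 381 long terminal repeats (LTRs) of retrotransposons and 274 origins. Origins had a median length of 247 bp, from 75 bp to 1256 bp. Chromosome III, at 312 kb, had 19 origins, or 1 per 16.4 kb. Chromosome XV, at 1089 kb, had 17, or 1 per 64.1 kb, and chromosome IV, at 1532 kb, had 32, or 1 per 47.9 kb. Across the 16 chromosomes the number of origins rose with length (Pearson's r = 0.717, two-sided permutation p = 0.00174, and Spearman's rho = 0.642, permutation p = 0.00833). Without the 2 chromosomes farthest from the median length, r was 0.468 (permutation p = 0.0906) and rho was 0.494 (permutation p = 0.0734), so the call, though not the direction, rested on those chromosomes.

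Neighbouring origins were spaced more evenly than random positions. The median distance was 37.4 kb, with quartiles of 21.5 kb and 56.5 kb over 258 distances, against a mean median of 27.5 kb for random placement. The coefficient of variation was 69.9%, against 104% for random placement with a central 95% range of 93.4% to 117% (two-sided permutation p = 0.0001, the smallest that 10000 draws can give). The longest distance was 173 kb, between ARS1607 and ARS1614 on chromosome XVI. It was followed by 146 kb between ARS813 and ARS818 on chromosome VIII, 136 kb between ARS216 and ARS220 on chromosome II, 130 kb between ARS1501 and ARS1516 on chromosome XV, and 119 kb between ARS1238 and ARS1232 on chromosome XII. The shortest was 0.223 kb between ARS601 and ARS602 on chromosome VI. The next were 0.33 kb between ARS302 and ARS303 and 0.703 kb between ARS303 and ARS320, both on chromosome III, 0.966 kb between ARS1012 and ARS1013 on chromosome X and 1.23 kb between ARS1622 and ARS1634 on chromosome XVI.

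Origins lay between genes. The midpoints of 266 of 274 origins were outside every protein-coding gene (97.1%, 95% interval 94.3% to 98.7%). Shifted origins gave 28.2% with a central 95% range of 23.0% to 33.6% (two-sided permutation p = 0.0001, the smallest possible). With the whole origin required to be outside genes, the share was 61.3% against 16.0% for shifted origins.

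Origins were more often between convergent genes, whose 3′ ends face each other, than random placement gave, and less often between divergent genes. Of 260 origins with a gene on each side, 89 lay between convergent genes (34.2%, 95% interval 28.5% to 40.3%), against 15.9% for placement in proportion to gap length. Divergent pairs held 47 origins (18.1%, 95% interval 13.6% to 23.3%), against 34.0%. Both differences had an adjusted permutation p of 0.00015. Tandem pairs held 124 origins (47.7%), against 50.1%, which did not pass the test (adjusted permutation p = 0.46). Gaps between convergent genes were the shortest, with a median of 230 bp, against 405 bp for tandem and 544 bp for divergent pairs. If every gap was taken as equally likely, the random share for convergent pairs was 25.9% (permutation p = 0.0020) and that for divergent pairs was 26.2% (permutation p = 0.0032).

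Over the whole genome, genes had no detectable orientation relative to the nearest origin. Of 5857 genes, 2906 were transcribed away from it (49.6%, 95% interval 48.3% to 50.9%), and shifted origins gave 50.3% with a central 95% range of 49.1% to 51.5% (two-sided permutation p = 0.29). Close to an origin fewer genes pointed away than shifted origins gave, and the difference from farther genes was not tested itself. The genes beside origins are among these, so the share is not independent of the counts of gene pairs above. Within 5 kb, 542 of 1186 genes pointed away (45.7%, 95% interval 42.8% to 48.6%), against 50.0% for shifted origins (permutation p = 0.0030). In 6 distance classes chosen after the file was seen, the class under 2.5 kb had 259 of 628 genes pointing away (41.2%, adjusted permutation p = 0.0006). The other 5 classes had between 49.3% and 51.9%, with adjusted permutation p of 0.53 or more. Beyond 5 kb the share was 50.6% (permutation p = 0.71).

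**Figure D2:**
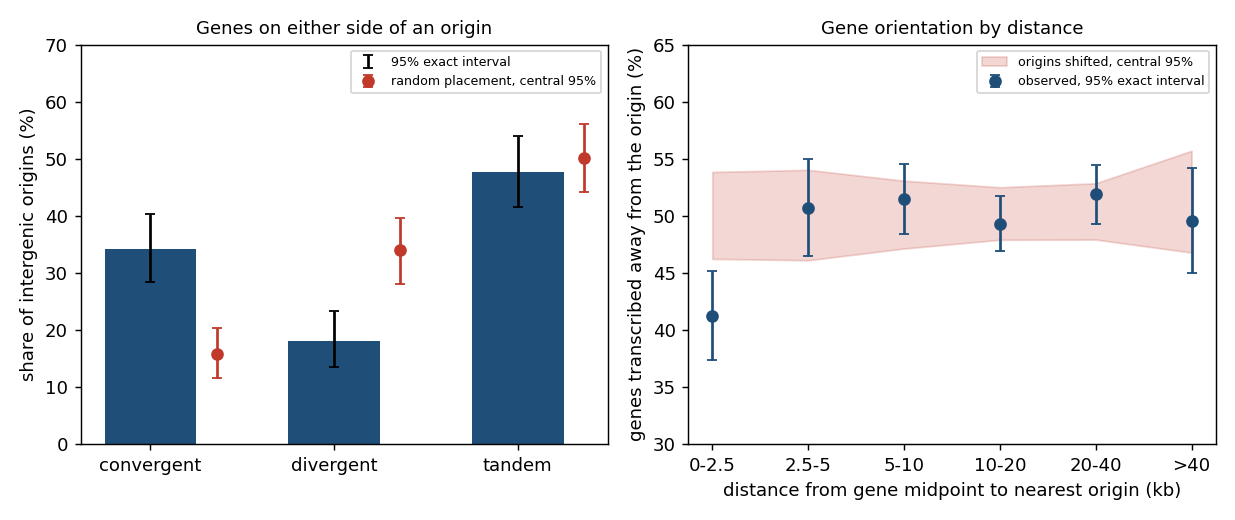
Left, share of 260 intergenic origins (vertical axis, %) between convergent, divergent and tandem genes as bars with exact 95% intervals, beside random placement as red points with the central 95% range. Right, share of genes transcribed away from the nearest origin (vertical axis from 30% to 65%) by distance in kb, as points with exact 95% intervals over a band for shifted origins. Convergent pairs held 34.2% against 15.9%, and only the class under 2.5 kb, at 41.2%, lay outside its band.

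None of the 7 gene lists differed from the other genes in orientation after adjustment by Fisher's exact test, and 1 of them had an unadjusted p under 0.05. That list was the 275 tRNA genes, of which 154 pointed away (56.0%, Fisher's exact p = 0.042, adjusted p = 0.29). The tRNA genes TG(GCC)M and TT(AGU)O1 lay 0.0155 kb and 0.127 kb from an origin midpoint, and TG(GCC)O1 and TE(UUC)P lay 51.0 kb and 79.4 kb away. Of 17 genes of glycolysis, 12 pointed away (70.6%, 95% interval 44.0% to 89.7%, Fisher's exact test, adjusted p = 0.33). TPI1, for triose phosphate isomerase, and TDH2, for glyceraldehyde-3-phosphate dehydrogenase, were nearest to an origin, at 0.751 kb and 0.888 kb. PFK2 and HXK2 were farthest, at 23.9 kb and 39.7 kb.

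Genes of ribonucleotide removal and dNTP supply pointed away in 9 of 13 cases (69.2%, 95% interval 38.6% to 90.9%, Fisher's exact test, adjusted p = 0.41). RNH203 and RNH202, for the other subunits of RNase H2, lay 2.46 kb and 3.11 kb from an origin and pointed away from it. TOP1 (topoisomerase I) and DUN1 (a checkpoint kinase) lay farthest, at 23.2 kb and 27.2 kb. Of 23 genes for replicative polymerases and their partners, 12 pointed away (Fisher's exact test, adjusted p = 0.93). RFA1, of the single-strand binding protein RPA, and RFC3, of the clamp loader, lay 2.33 kb and 2.94 kb from an origin, and RFC2 and the ligase gene CDC9 lay 27.5 kb and 42.4 kb away. Of 25 genes for origin licensing and the helicase, 14 pointed away (Fisher's exact test, adjusted p = 0.93). MCM6 and CDC6 lay 1.67 kb and 2.40 kb from an origin, and MCM10 and ORC6 lay 44.1 kb and 47.3 kb away.

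The 10 histone genes had a median distance of 2.01 kb to the nearest origin, against 11.2 kb for 138 cytoplasmic ribosomal protein genes. The medians of the remaining lists ran from 4.25 kb for glycolysis to 16.1 kb for replicative polymerases. These medians were not tested against each other. Of the histone genes, 4 pointed away (Fisher's exact test, adjusted p = 0.93). HTB1 (histone H2B) and HHF1 (histone H4) were nearest, at 0.601 kb from ARS428 and 0.741 kb from ARS209, and HHO1 and HTZ1 were farthest, at 19.6 kb and 26.1 kb. Of the ribosomal protein genes, 69 pointed away and 69 toward (Fisher's exact test, adjusted p = 0.93). RPS19B and RPL12B lay 0.704 kb and 0.847 kb from an origin, and RPL7B and RPS7A lay 57.3 kb and 60.2 kb away. Among the short lists, even that of 25 genes had an interval of 34.9% to 75.6%, so a moderate difference in orientation was not detectable in them.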

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

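The alternatives had been chosen before the data were examined, except the one that left out the genes beside each origin. Of 48 alternative values, 41 kept their direction and their side of the threshold. For genes within 5 kb of an origin, the share transcribed away was 45.7% (permutation p = 0.0030), where all genes gave 49.6% (permutation p = 0.29). In 6 alternatives the difference changed its sign relative to all genes or to the whole list, and neither value passed the test. The share for all genes lay below that of shifted origins, but other shares lay above theirs. These were the shares measured from the 5′ end of the gene feature (51.3%, permutation p = 0.075), beyond 5 kb (50.6%, permutation p = 0.71) and within 5 kb without the genes beside each origin (49.5%, permutation p = 0.66). The last of these changes 2 choices at once, and set against the 45.7% for all genes within 5 kb it lost the call. Within 10 kb of an origin, 3 of 9 licensing and helicase genes pointed away (33.3%), against 56.0% at any distance. Of the ribosomal protein genes there, 30 of 64 did so (46.9%), against 50.0%. Of the histone genes there, 3 of 6 did so (50.0%), against 40%. Each of these lists changed sides relative to the other genes. The cause was not tested. Leaving out each chromosome in turn gave 49.2% to 49.9% of all genes. Adding the 2 dubious reading frames changed almost nothing and tests little. The excess of origins between genes and between convergent genes and the even spacing kept their direction and passed under each alternative tried. None of the 7 gene lists passed under either of their alternatives, with a lowest adjusted p of 0.074 by Fisher's exact test, for glycolysis within 10 kb. No paired analysis was possible because no values of the libraries were analysed here. No read depth enters these values, and the number of annotated features limits their precision. Only 4 of the 274 origins carry a qualifier of experimental evidence, which leaves the evidence for the others unknown here. The activity of the origins was not examined.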

Other observations

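The tests on coding length, and that of genes near origins without the genes beside them, were chosen after those patterns were seen. The test of origins against tRNA genes had been framed for origins lying away from tRNA genes, and the distance came out shorter.

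LTRs lay close to tRNA genes. The median distance from 381 LTRs to the nearest tRNA gene was 0.554 kb, against 16.8 kb when the tRNA genes were shifted around their chromosomes as the origins were above, with a central 95% range of 12.4 kb to 21.5 kb (adjusted permutation p = 0.0004). Within 1 kb of a tRNA gene were 250 LTRs (65.6%), against 4.62% for shifted genes. Both values lay outside what independent placement along whole chromosomes gave. Independent placement of LTRs and tRNA genes within the sequence between protein-coding genes was not tested. The median distance from origins to the nearest tRNA gene was 14.4 kb, against 17.3 kb with a shifted range of 14.6 kb to 20.1 kb, a value just outside that range that did not pass the threshold after adjustment over 4 pairs of features (unadjusted permutation p = 0.036, adjusted p = 0.073). Within 1 kb of a tRNA gene were 22 origins (8.03% against 4.60%, adjusted permutation p = 0.013). Within 1 kb of an LTR were 35 origins (12.8% against 4.82%, adjusted permutation p = 0.0002). The median distance of origins to LTRs was 19.8 kb against 21.8 kb (adjusted permutation p = 0.30). The shifts did not keep features outside protein-coding genes, where most origins lay. A shared place between genes could raise these shares within 1 kb and was not tested. Centromeres had a median distance of 6.68 kb to the nearest origin, against 12.0 kb (adjusted permutation p = 0.15). Of 16 centromeres, 3 lay within 1 kb of an origin (18.8% against 5.19%, adjusted permutation p = 0.045). This share was at the edge of the shifted range of 0% to 18.8%. Medians and shares were each adjusted over the 4 pairs, not together, and the p of 0.045 was the same before adjustment.

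The lower share of genes pointing away within 5 kb of an origin may lie in the genes directly beside origins. The 521 such genes pointed away in 40.9% of cases, against 51.9% for shifted origins (permutation p = 0.0001, the smallest possible). The other 665 genes within 5 kb pointed away in 49.5% of cases, inside the shifted range of 45.1% to 52.3%. An excess of origins between convergent genes puts genes that point toward the origin on both sides of it. The share among genes beside origins therefore largely counts that excess again and is no separate support for it. Whether it reflects where origins can act or how they were found and curated stays open, and neither was tested.

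Of 5860 coding sequences, 91 had a length other than the stated protein requires (1.55%), 42 longer and 49 shorter. Among the 5 largest differences were those at LEU2 (-1037 bp), an edited locus, and at FLO1 (-506 bp), YIL014C-A (-305 bp) and FLO9 (-289 bp). FLO1 and FLO9 encode flocculins, cell wall proteins with internal repeats. Retrotransposon genes, genes lying wholly within 25 kb of a chromosome end and edited genes made up 24 of the 91 (26.4%, 95% interval 17.7% to 36.7%) and so do not account for most of the list. Repeats inside genes were not counted, nor were genes that straddle the 25 kb limit, and FLO1 and FLO9, which straddle it, are among the other 67. Of these 67, 30 differed by 1 bp, 6 by 2 bp and 19 by 3 bp, and 25 (37.3%, 95% interval 25.8% to 50.0%) differed by a multiple of 3. Changes that ignore the reading frame would give equal shares only if all lengths were equally frequent, and differences of 3 bp outnumbered those of 2 bp (exact binomial test, two-sided, p = 0.015). Whether the changes ignore the reading frame, as errors of sequence or assembly would, therefore stays open. Coding sequences with experimental evidence made up 65.9% of the 91 and 80.9% of the others (Fisher's exact test, two-sided, p = 0.00073). Among the genes outside those classes these were 74.6% and 83.2% (Fisher's exact test, p = 0.071). No biological explanation of the length differences was tested.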
